A study of Mus musculus with 11 samples.

How the data were processed

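RNA from the small intestine of mice was sequenced in 11 libraries, 3 labelled ND, 4 labelled HFD and 4 labelled HLJDD. Per the labels' protocols, total RNA was extracted with TRIzol, a phenol-based reagent, and libraries were made with a VAHTS Universal V6 RNA-seq kit. Per the submitters' processing notes, the tools were fastp (read trimming), HISAT2 (alignment), HTSeq (counting reads per gene) and R 3.2.0, with the mm10 mouse genome. The gene annotation, the strand setting and the other tool versions are not given in the sources used here. The deposited values are FPKM, fragment counts divided by gene length and by the library total, and the authors gave one value per gene symbol and library for 24294 symbols. The same values stood in the single files and in a table of the whole series, with 0 differences.

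The depth was worked out from the FPKM values, because each gene's values are whole multiples of what 1 read is worth in a library. Whole reads came back for 24292 of the 24294 symbols in all libraries (99.99%), and the largest distance from a whole number was 0.0019 reads. The recovered totals ran from 30101888 to 37943272 reads per library. A gene of 1 kb at 1 FPKM therefore rested on 30.1 to 37.9 reads. Genes below that level carry the largest counting error. Reads from near-identical copies (the Defa, Reg3, Ifit and Oas families, class II histocompatibility genes) and from overlapping or antisense genes may have been split or merged in counting, so values of single members are uncertain.

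Libraries were grouped by their titles. Changes are differences between group means of log2(FPKM + 1), a scale that understates the change of low genes. Genes with at least 1 FPKM in at least 3 libraries were kept (10764). The test was limma (version 3.58.1 in R 4.3.3), two-sided, with a variance trend, all 11 libraries in one fit and no covariate. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 and no minimum fold. Levels are given as mean FPKM ± SD over the libraries of a group (n = 3 for ND, n = 4 for HFD and n = 4 for HLJDD). Hormone genes were also tested by an exact two-sided permutation test of the group means. With 3 libraries against 4 the smallest p it can give is 0.0286, from 35 arrangements.

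Before the data were examined, 47 gene lists for pathways, cell types, stretches of gut and RNA handling were fixed, and the 41 with at least 5 kept members were tested. For each list, members past the threshold were counted over all genes and adjusted over the list alone. Lists were tested against all other genes with camera from limma, at a preset correlation between genes of 0.01, adjusted over the 41 lists. Camera with an estimated correlation was run beside it, and no list passed with it in any comparison (lowest adjusted p = 0.137 for HFD against ND, 0.123 for HLJDD against HFD and 0.0749 for HLJDD against ND). Fry from limma was run as well. It asks whether the members change, not whether they change more than other genes, so a shift of all genes enters it. Fry called 10 of 41 lists in HFD against ND, 0 in HLJDD against HFD and 11 in HLJDD against ND. The genes named were also set by a rule beforehand. It takes the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, leaving out unnamed gene models, pseudogenes and receptor segments. If none pass, it takes the 10 smallest p-values. It adds up to 4 members with the smallest adjusted p of each list reported, and Gip, Gcg, Cck, Sct and Sst in every comparison. Gipr, the receptor of the Gip product, did not reach the expression filter. Mitochondrial and histone symbols of the lists were matched through older names. Gene positions come from a RefSeq gene table of GRCm38.p6, the assembly that mm10 stands for.

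Alternatives to each step were also fixed beforehand. They were another pseudocount (0.1), no filter or a mean of at least 5 FPKM, scaling to equal sums (TPM), median-ratio scaling, quantile normalization, equal sums without the 50 most abundant genes, robust variance estimates, weights per library, a fit of only the 2 groups compared, the replicate number as a block, limma-voom on the recovered reads, and leaving out each library in turn. A further 4 were added after the data were seen. Among them were leaving out the 2 libraries with the highest mitochondrial share and using scores of the proximal and distal gut lists as terms. Every fit with these region scores was run on median-ratio scaled values, so it changed 2 choices at once. Each score is a mean over the list's members, so members such as Pyy, Nts, Fabp6, Slc10a2 and Gata4 were partly adjusted for themselves. Groups made up 0.413 and 0.789 of the variance of the proximal and distal score. Smaller changes or lost calls in these fits therefore cannot separate region from group.

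The limma fit was tested on simulated data with 10764 genes, of which 100 were changed by 1 and 100 by 2 on the log2 scale. For HFD against ND, limma recovered 77% and 93% of them with 6 false calls. For HLJDD against HFD it recovered 74% and 98% with 8 false calls, and for HLJDD against ND 72% and 96% with 7. Camera was tested on a separate simulation, in which it called the list of 20 genes raised by 0.7 in HFD and 0 of 40 other lists. The permutation test was not simulated. None of the 55 pairs of libraries matched within sampling noise (chi-square per gene of at least 38.2), which does not show that they come from separate animals. Each library was treated as 1 sample. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots. No reads were realigned.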

Results

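RNA from the small intestine of mice was measured in 11 libraries of 3 groups, which the labels call ND (n = 3), HFD (n = 4) and HLJDD (n = 4). Huang Lian Jiedu Decoction, a herbal preparation named in the series title, has the initials of the last group. The title concerns obese mice, lipid metabolism and gastric inhibitory polypeptide, the hormone encoded by Gip. The labels used here neither spell out ND and HFD nor state which diet the HLJDD mice ate, and the stretch of small intestine sampled is not given. They do not say that each library comes from a separate animal, so p-values measure only the spread between these libraries, which may be technical. Each library held from 30101888 to 37943272 reads in genes, worked out from the deposited FPKM values. Log2 changes are differences between group means of log2(FPKM + 1), and levels are means ± SD.

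Transcripts of the mitochondrial genome took 10.4% to 19.3% of the reads in 9 libraries, 32.4% in HFD replicate 1 and 40.7% in HLJDD replicate 2. These 2 libraries also had the lowest totals, 31842012 and 30101888 reads. The median log2 change of all 10764 genes tested was -0.205 for HFD against ND, 0.061 for HLJDD against HFD and -0.127 for HLJDD against ND. After median-ratio scaling it was -0.011, -0.001 and 0.004, so counts after this scaling are given beside those as deposited. On scaled values the first principal component (56.7% of the variance) placed the ND libraries at -51.7, -43.3 and -32.4 and the other 8 libraries between 1.79 and 34.0.

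**Figure D1:**
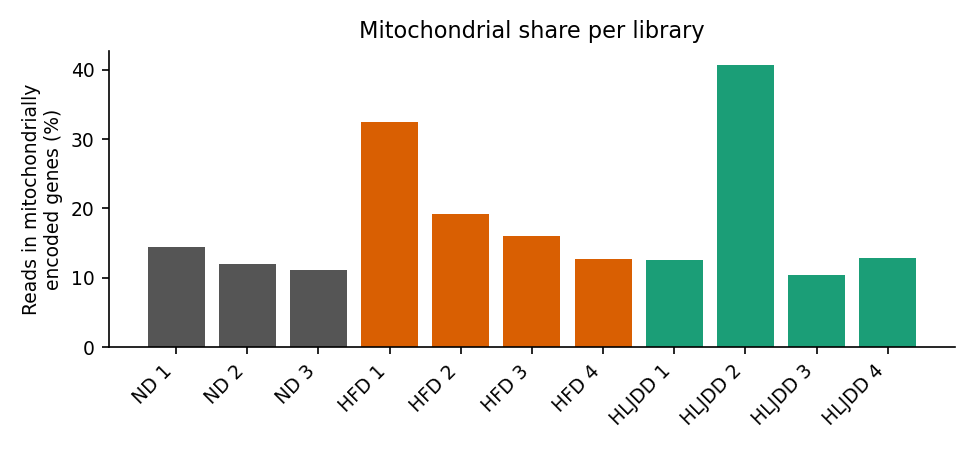
Share of reads in mitochondrially encoded genes (percent, vertical axis) in each library (horizontal axis), with 1 bar per library coloured by group. HFD replicate 1 (32.4%) and HLJDD replicate 2 (40.7%) stand above the other 9 libraries (10.4% to 19.3%).

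Gip, which encodes the incretin hormone released by K cells of the upper gut (mm10 chromosome 11, 96024532 to 96030831), was measured in every library. Its level was 32.7 ± 14.8 FPKM in ND (18.9, 30.8 and 48.3), 100.7 ± 12.8 FPKM in HFD (range 81.8 to 109.1) and 68.9 ± 16.1 FPKM in HLJDD (range 50.5 to 88.8). After median-ratio scaling the levels were 29.6 ± 14.3, 106.5 ± 2.17 and 68.3 ± 6.18, and the 4 HFD libraries (103.4 to 108.1) lay above all 4 HLJDD libraries (62.6 to 77.0).

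**Figure D2:**
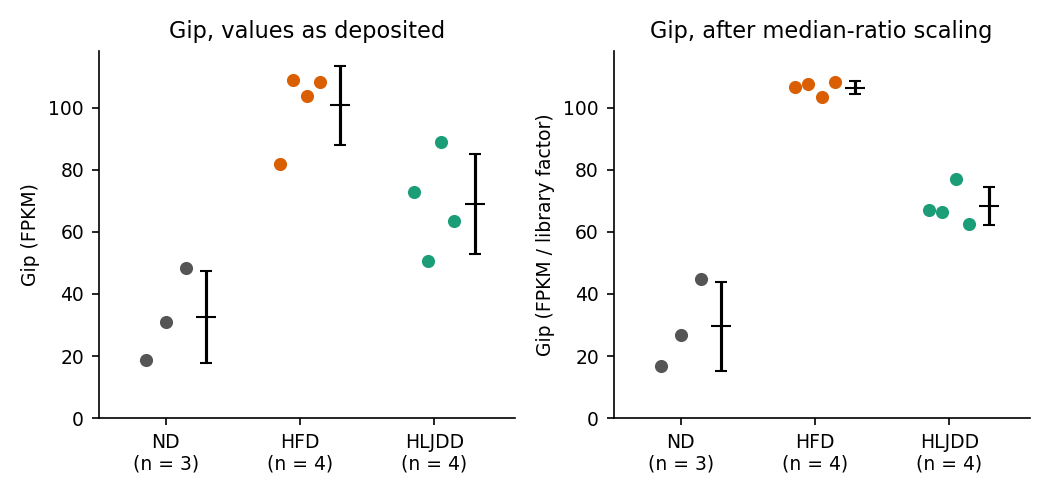
Gip level in each library, in FPKM as deposited (left) and divided by the library's median-ratio factor (right). Points are libraries, the bar beside them is the group mean with its SD, and group means run from 32.7 (ND) to 68.9 (HLJDD) and 100.7 FPKM (HFD) as deposited.

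The comparison of HFD with ND asks what the HFD regimen changed in the small intestine. The gene for the chylomicron protein Apoa4 (chromosome 9, 46240844 to 46243458) rose from 1429.9 ± 1310 FPKM in ND (n = 3) to 18326 ± 2512.5 FPKM in HFD (n = 4), a log2 change of 4.27 (SE 0.59). Fabp6, the bile acid carrier of the ileum (chromosome 11, 43596040 to 43601562), fell from 5640 ± 4801 to 2.86 ± 1.34 FPKM, a log2 change of -9.66 (SE 0.85). Camera called interferon-stimulated (26 of 38 lower), cholesterol synthesis (20 of 26) and distal gut genes (9 of 14) lower in HFD, and fat absorption (8 of 25 higher) and goblet cell genes (5 of 13) higher. These 5 calls were lost with an estimated correlation (adjusted p = 0.137 to 0.53). Fry, which does not compare with other genes, called the interferon (adjusted p = 0.00089), cholesterol (0.0026), distal (0.0064) and goblet lists (0.0026), but not fat absorption (0.11). In all, 1786 of 10764 genes changed by limma, 545 higher and 1241 lower, and after median-ratio scaling 1351 were higher and 1344 lower. Camera called 16 of 41 lists higher and 7 lower, and 0 of them passed with an estimated correlation.

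With Apoa4, the 10 largest rises among genes whose groups did not overlap were in Enpp3, Slc46a1 (the intestinal folate transporter), Adh1, Ada, Bbox1, Tm4sf4, Aadac, Reg1 and Adh4, and the other 9 rose by 3.29 to 4.19 on the log2 scale. Tm4sf4, a membrane protein gene (chromosome 3, 57425410 to 57441677), rose from 50.6 ± 3.72 to 589.5 ± 127.6 FPKM (log2 change 3.49, SE 0.19, adjusted p = 2.12e-06). The largest falls after Fabp6 were in Plb1, Saa1, Slc10a2, Fam151a, Tmigd1, Duoxa2, Reg3g, Mgat4c and Duox2, with log2 changes of -6.58 to -4.68. Saa1 encodes an acute phase protein that gut bacteria induce in the ileum. The calls of Reg1 (adjusted p = 0.0397) and Reg3g (0.0215) were both lost without ND replicate 1 (0.133 and 0.0814), ND replicate 2 (0.123 and 0.0793) or ND replicate 3 (0.079 and 0.0551). The Reg1 call was also lost without HFD replicate 1 (0.0576), HFD replicate 3 (0.0873) or HFD replicate 4 (0.0735). With gut-region scores as terms, on median-ratio scaled values, the log2 changes of Reg1, Ada, Fam151a and Reg3g were far smaller. They were 0.102 for Reg1 (adjusted p = 0.978, range over the alternatives 1e-05 to 0.978) and 0.256 for Ada (0.884, range 1.6e-06 to 0.884). For Fam151a the change was -0.44 (0.899, range 6.6e-06 to 0.899) and for Reg3g -0.63 (0.915, range 0.00016 to 0.915). Of these rises and falls, only those of Adh1, Bbox1, Tm4sf4, Fabp6, Saa1, Tmigd1 and Duox2 stayed past the threshold in that fit.

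Among 18 hormone and granule genes of enteroendocrine cells, 3 rose and 3 fell in HFD against ND (3 and 5 adjusted over the list alone, 3 and 3 after scaling). Gip rose by 1.68 (SE 0.27, adjusted p = 0.00218; exact permutation p = 0.0286, the smallest that 35 arrangements allow). Over ND replicates 1, 2 and 3 it rose (18.9, 30.8 and 48.3 FPKM) while the ileal gene Fabp6 fell (9821, 6702 and 397 FPKM). As Gip is a gene of the upper gut, an effect of the diet on it cannot be told apart from a more distal stretch in ND. Ghrl, the ghrelin gene (chromosome 6, 113716119 to 113719911), rose from 2.89 ± 0.78 to 10.4 ± 1.86 FPKM. Pyy, made by L cells that are most frequent in the lower gut, fell from 33.8 ± 11.2 to 4.73 ± 2.87 FPKM. With gut-region scores as terms its log2 change was -0.04 (adjusted p = 0.976, range over the alternatives 3.7e-06 to 0.976). Pyy is in the list behind the distal score, so that fit partly adjusted it for itself. The granule gene Scg2 fell by 1.53 on the log2 scale. The remaining 2, named after their values were seen, were Chga among the higher and Pcsk1 among the lower genes as deposited. The Scg2 call was lost without ND replicate 1 (adjusted p = 0.145), ND replicate 2 (0.118), HFD replicate 1 (0.0703) or HFD replicate 3 (0.0509), and with the region scores as terms its log2 change was -0.0723 (0.954, range over the alternatives 1.2e-06 to 0.954). Gcg (log2 change -1.26), Cck (0.35), Sct (-0.24) and Sst (-0.51) did not pass, at adjusted p of 0.0711 to 0.476. The log2 change of Sct was 0.0049 after scaling (adjusted p = 0.992). The list as a whole was not called (camera adjusted p = 0.594, direction up, while its median log2 change was -0.45).

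Of 25 fat absorption and chylomicron genes, 8 rose and none fell (9 adjusted over the list alone, 15 after scaling). Examples besides Apoa4 are Fabp1, the fatty acid carrier of the upper gut (2269 ± 1978 to 12448 ± 1508 FPKM), Acsl3, a fatty acid activating enzyme (5.26 ± 0.38 to 17.3 ± 2.39), and Clps, the colipase that the pancreas makes (2.05 ± 0.25 to 11.4 ± 3.83). Of the 27 pancreatic acinar genes listed, 6 were kept, and of these 3 rose and none fell, in both counts (4 after scaling). Camera called the acinar list higher (adjusted p = 5e-06, and 0.137 with an estimated correlation). The 3 were Clps and Pnliprp2, which are also in the Paneth list, and Zg16, which is also in the goblet list. Their rise therefore cannot be assigned to pancreatic cells. Camera called the fat absorption list higher (adjusted p = 1.6e-07; adjusted p = 0.513 with an estimated correlation). Of 31 fatty acid oxidation and PPAR-alpha genes, 8 rose and 2 fell (10 and 2 adjusted over the list alone, 14 and 2 after scaling), and the list was called higher (adjusted p = 0.00011; adjusted p = 0.631 with an estimated correlation). The 2 that fell were Vnn1 and Angptl4, which fell by 2.22 and 1.20 on the log2 scale.

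Cholesterol synthesis genes fell together, 20 of 26 with none higher (22 lower and 1 higher adjusted over the list alone, 21 lower after scaling). Sqle, which catalyses an early oxygen-dependent step, fell from 35.3 ± 14.7 to 4.71 ± 1.78 FPKM, and the isomerase gene Idi1 from 14.3 ± 6.74 to 1.69 ± 0.44. Camera called the list lower (adjusted p = 7.5e-09; adjusted p = 0.513 with an estimated correlation). Of 14 fatty acid synthesis genes, 1 rose and 5 fell (2 and 6 adjusted over the list alone, 2 and 5 after scaling), and the list was not called (adjusted p = 0.594). Its desaturase Scd2 fell from 30.03 ± 1.32 to 3.66 ± 1.85 FPKM. Of 8 bile acid transport and FXR target genes, 1 rose and 5 fell, in both counts and after scaling. These 5 include Slc10a2, the ileal bile acid importer (135 ± 124 to 0.264 ± 0.193 FPKM), Slc51a, part of the basal exporter (445 ± 123 to 77.1 ± 22.9), and Nr1h4, which encodes FXR (35.3 ± 10.99 to 9.48 ± 1.79). The bile acid list was called lower (adjusted p = 0.0087; adjusted p = 0.513 with an estimated correlation).

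Markers of the stretch of gut moved in the same comparison. Of 14 distal small intestine genes, 9 fell and none rose (10 adjusted over the list alone, 9 after scaling), with camera adjusted p = 0.00067 (adjusted p = 0.53 with an estimated correlation). Of 12 proximal genes, 4 rose and 2 fell (6 and 2 adjusted over the list alone, and after scaling), with camera adjusted p = 0.0019, 0.056 after scaling (adjusted p = 0.53 with an estimated correlation). Gata4, a transcription factor of the upper gut, was at 30.5 ± 4.85 FPKM in HFD and 16.6 ± 7.53 in ND (adjusted p = 0.028). Its call was lost without ND replicate 1 (adjusted p = 0.134), ND replicate 2 (0.1), HFD replicate 3 (0.0647) or HFD replicate 4 (0.0558). Within ND, Fabp6 stood at 9821, 6702 and 397 FPKM in replicates 1, 2 and 3. Fabp6 and Slc10a2 are in both the bile acid and the distal list, Pyy and Nts in the hormone and the distal list, Fabp1 in the fat absorption, enterocyte and proximal lists, and Clps in the fat absorption, Paneth and acinar lists, so these lists share members.

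**Figure D3:**
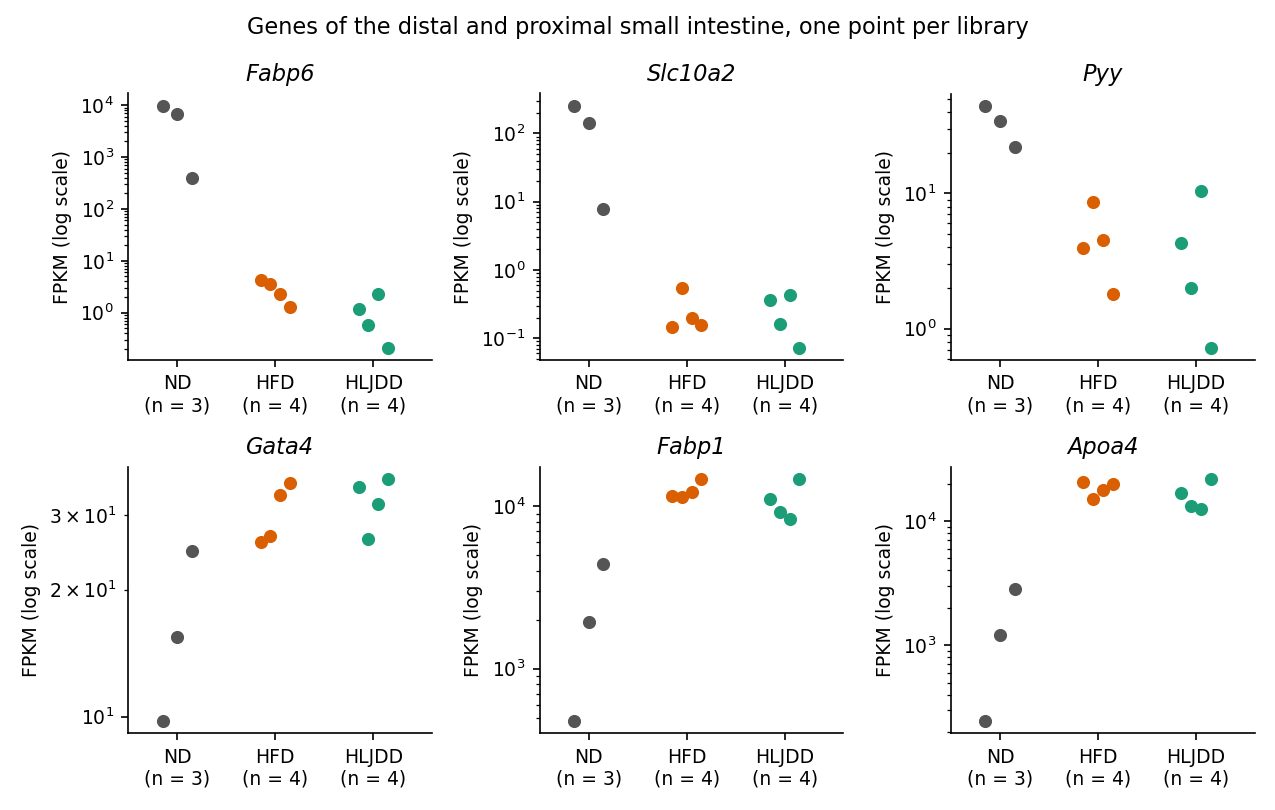
FPKM on a log axis for 3 distal genes (Fabp6, Slc10a2, Pyy) and 3 genes high in the upper gut (Gata4, Fabp1, Apoa4), with 1 point per library and groups along the horizontal axis. Fabp6 lies between 397 and 9821 FPKM in the ND libraries and averages 2.86 FPKM in HFD and 1.06 in HLJDD.

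Interferon-stimulated genes fell in HFD against ND, 26 of 38 with none higher (28 adjusted over the list alone, 20 after scaling). Ifit1bl1 fell from 38.8 ± 6.55 to 5.53 ± 0.24 FPKM, the 2'-5' oligoadenylate synthetase gene Oas1a from 25.1 ± 5.81 to 5.62 ± 0.73, and Ifit3 from 6.68 ± 0.62 to 1.98 ± 0.21. Camera called the list lower (adjusted p = 1.3e-11; adjusted p = 0.284 with an estimated correlation). Of 20 antimicrobial and microbe-induced genes, 4 rose and 9 fell (6 and 12 adjusted over the list alone, 4 and 8 after scaling). Among them Nos2, the inducible nitric oxide synthase, fell from 35.6 ± 9.11 to 0.667 ± 0.9 FPKM, and the hydrogen peroxide producing oxidase Duox2 from 46.3 ± 12.5 to 1.02 ± 1.2. That list was not called in HFD vs ND (camera adjusted p = 0.247), but was called lower without HFD replicate 1 (0.0477). Fry, which does not compare with other genes, called it lower with all libraries (adjusted p = 0.0026).

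Cell type markers differed as well. Of 13 goblet cell genes, 5 rose and none fell (6 adjusted over the list alone, 7 after scaling; camera adjusted p = 9e-07; adjusted p = 0.137 with an estimated correlation). The lectin gene Zg16 rose from 910.5 ± 315.5 to 2901 ± 215 FPKM and the trefoil factor Tff3 from 557.8 ± 163.9 to 1099 ± 62.4. Of 9 tuft cell genes, 5 fell and none rose (6 adjusted over the list alone, 4 after scaling), among them Sucnr1 (1.53 ± 0.396 to 0.369 ± 0.187), with camera adjusted p = 0.0076 (adjusted p = 0.622 with an estimated correlation). The tuft cell call was lost in the HFD vs ND fit without ND replicate 1 (adjusted p = 0.0555). Of 17 mature enterocyte genes, 6 rose and none fell (7 higher and 1 lower adjusted over the list alone, 10 and 1 after scaling; camera adjusted p = 3.2e-05; adjusted p = 0.53 with an estimated correlation), including the ecto-nucleotidase Nt5e (5.73 ± 2.22 to 62.0 ± 24.1). Of 12 B and plasma cell genes, 2 were higher over all genes, 12 adjusted over the list alone and 4 after scaling (camera adjusted p = 1.9e-07; adjusted p = 0.513 with an estimated correlation). The 2, Mzb1 and Tnfrsf13b, each lost the call without ND replicate 1 (adjusted p = 0.107 and 0.132) and in at least 5 other fits without 1 library. The HFD libraries were uneven in some of these genes. Cd79a stood at 99.3, 59.3, 22.8 and 1.31 FPKM in HFD replicates 1 to 4, the last within the ND range (0.752 to 1.47). Jchain, at 70.0, 151.1, 142.3 and 121.0, was above ND (33.7 to 62.1) in each. The source of this spread was not tested. Of 13 adipocyte genes, 3 rose (Cidec, Pparg and Pck1) and none fell, in both counts (5 rose after scaling). Enterocytes also express these 3 genes, so their rise need not reflect fat cells. Camera called the adipocyte list higher (adjusted p = 3.4e-05, and 0.284 with an estimated correlation). The Pck1 call was lost without ND replicate 1 (adjusted p = 0.0552).

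Of 18 protein digestion and amino acid transport genes, 7 fell and none rose (10 adjusted over the list alone, 9 after scaling), including the brush border protease Mep1a (312.3 ± 110.3 to 31.2 ± 9.96 FPKM) and the glutamate transporter Slc1a1 (52.1 ± 21.7 to 6.11 ± 3.16). Camera called that list lower (adjusted p = 0.035; adjusted p = 0.819 with an estimated correlation), but not in HFD vs ND without ND replicate 3 (0.103) or HFD replicate 2 (0.0601). Of 18 carbohydrate genes, 2 rose, among them Pck1, and none fell, in both counts (7 rose after scaling). The Pck1 call was lost without ND replicate 1 (adjusted p = 0.0552). The carbohydrate list was called higher (adjusted p = 0.00021; adjusted p = 0.622 with an estimated correlation). Of 33 xenobiotic and retinoid genes, 8 rose and 2 fell, in both counts (9 and 2 after scaling; adjusted p = 1.4e-06; adjusted p = 0.622 with an estimated correlation). Rbp2, the retinol carrier of enterocytes, rose from 1601 ± 743 to 10526 ± 1569 FPKM, and Cyp2c55 fell from 77.3 ± 7.18 to 6.58 ± 3.23.

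Of 36 nuclear-encoded oxidative phosphorylation genes, 8 rose and none fell, in both counts (17 after scaling; camera adjusted p = 9e-07; adjusted p = 0.53 with an estimated correlation). Ndufa1, a complex I subunit, rose from 138.2 ± 32.7 to 238.6 ± 20.7 FPKM. None of the 13 mitochondrially encoded transcripts passed in HFD against ND by limma, with a median log2 change of 0.54, and their camera call (adjusted p = 0.0018) was at 0.0715 after scaling (adjusted p = 0.631 with an estimated correlation). Of 23 unfolded protein and amino acid response genes, 1 rose and 9 fell (2 and 15 adjusted over the list alone, 2 and 13 after scaling), among them the endoplasmic reticulum co-chaperone gene Dnajb9 (96.9 ± 9.53 to 45.6 ± 5.46). That list was at camera adjusted p = 0.0542 as deposited and 0.0031 after scaling. It was called lower without ND replicate 1 (0.0353), ND replicate 2 (0.0349), HFD replicate 1 (0.0259) or HFD replicate 4 (0.0278). Of 16 circadian genes, 3 rose and 2 fell (4 and 3 adjusted over the list alone, 5 and 1 after scaling), with Dbp at 44.8 ± 9.96 FPKM in HFD and 15.4 ± 2.07 in ND. The circadian call (adjusted p = 0.0398; adjusted p = 0.671 with an estimated correlation) was lost in HFD vs ND without ND replicate 3 (0.14), HFD replicate 3 (0.0523) or HFD replicate 4 (0.0634).

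The count of 1786 genes was 617 without ND replicate 1, 638 without ND replicate 2, 1189 without HFD replicate 3, 3314 without HLJDD replicate 2 and 3349 without both high-mitochondrial libraries. After scaling, leaving out 1 library gave 1271 (without ND replicate 2) to 3108 genes (without HLJDD replicate 2), with 1307 without ND replicate 1. A fit with scores of the proximal and distal lists as terms, on median-ratio scaled values, was added after the data were seen. It called 171 genes, where scaling alone called 2695. The scores differ between the groups, which made up 0.413 (proximal) and 0.789 (distal) of their variance, so the lower count does not separate region from group. The change of Gip in this fit was 1.61 (adjusted p = 0.125, range over the alternatives 1.4e-07 to 0.125). In that fit the change of Apoa4 was 2.27 (adjusted p = 0.269, range 3.5e-07 to 0.269), so its call was lost, while Fabp6 stayed past the threshold (0.0388, the highest over the alternatives).

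**Figure D4:**
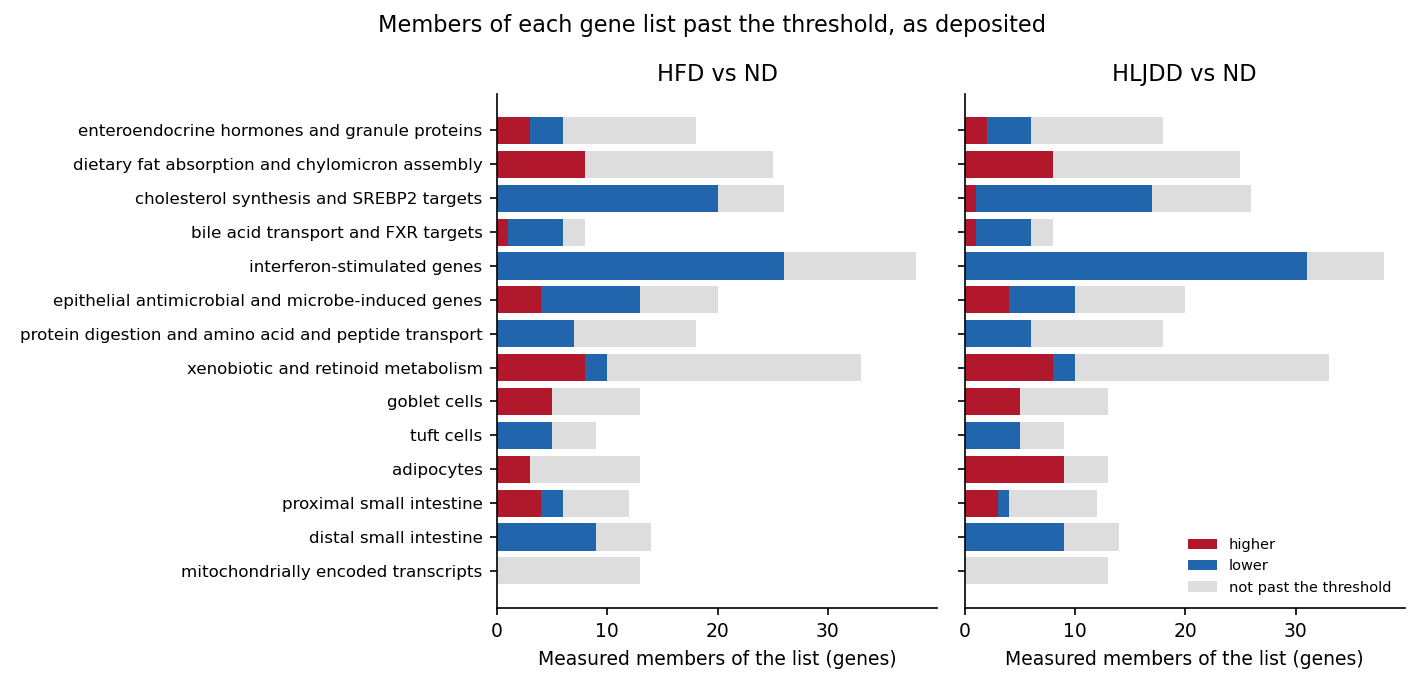
Number of measured genes of each list (horizontal axis) that were higher (red), lower (blue) or not past the threshold (grey) in HFD against ND (left) and HLJDD against ND (right), as deposited. Interferon-stimulated genes were lower in 26 and 31 of 38 cases, cholesterol synthesis genes in 20 and 16 of 26, and adipocyte genes higher in 3 and 9 of 13.

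The comparison of HLJDD with HFD asks what the decoction group changed relative to HFD, and no single gene passed. Gip was at 68.9 ± 16.1 FPKM in HLJDD (n = 4) and 100.7 ± 12.8 in HFD (n = 4), a log2 difference of -0.56 (SE 0.25). Camera called adipocyte genes higher and T cell and interferon-stimulated genes lower in HLJDD, with no member past the threshold over all genes. These calls were lost with an estimated correlation (adjusted p = 0.123, 0.123 and 0.277). By limma 0 genes were called, with 186 at an unadjusted p under 0.05. Median-ratio scaling gave 0 (581 unadjusted) and limma-voom 0 (172 unadjusted), while weights per library gave 3807. Camera called 4 of 41 lists higher and 10 lower, and 0 of them passed with an estimated correlation or with fry. Without HLJDD replicate 2, 1 gene passed, the stearoyl desaturase Scd1 (log2 difference 1.34, adjusted p = 0.0369; range over the alternatives 7.2e-06 to 1), and with median-ratio scaling in addition no gene passed.

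For Gip the exact permutation p was 0.0571 as deposited and 0.0286 after scaling (70 arrangements), and the adjusted p from limma was 0.999 over all genes and 0.835 adjusted over the list alone (0.834 and 0.28 after scaling). With weights per library the adjusted p was 0.0062, and the range over the alternatives was 0.0062 to 1. Cck (log2 difference 0.02), Gcg (0.30), Sct (-0.14) and Sst (0.22) did not pass. None of the 18 enteroendocrine genes passed in either count by limma, while camera called the list lower (adjusted p = 0.00055; adjusted p = 0.675 with an estimated correlation), with Chga at 30.4 ± 2.44 against 37.7 ± 9.47 FPKM and Nts at 44.9 ± 30.5 against 64.9 ± 28.2.

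The 10 genes with the smallest p, none past the threshold in HLJDD against HFD, had the following log2 differences. Higher in HLJDD were Retn (1.56), Lep (1.18), Scd1 (1.08), Plin1 (0.87), Hsph1 (0.85) and Tnnt3 (0.40). Lower were Ido1 (-1.19), Sprr1a (-0.97), Gzmb (-0.90) and Nkg7 (-0.45). Retn, Lep and Plin1 encode resistin, leptin and perilipin, products of fat cells, and Gzmb and Nkg7 are granule genes of cytotoxic lymphocytes.

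Of 13 adipocyte genes, 0 passed over all genes by limma and 9 were higher adjusted over the list alone, with none lower. Retn was at 6.52 ± 3.08 against 1.46 ± 0.895 FPKM, Lep at 3.50 ± 2.14 against 0.889 ± 0.47, and Adipoq, the adiponectin gene, at 13.9 ± 5.30 against 5.28 ± 3.02. Camera called the list higher (adjusted p = 3.2e-11; adjusted p = 0.123 with an estimated correlation), with a median log2 difference of 1.18 and 1.11 after scaling. Of 9 T cell and intraepithelial lymphocyte genes, 0 passed over all genes and 3 were lower adjusted over the list alone. These were Nkg7 (0.722 ± 0.108 against 1.35 ± 0.078 FPKM), the granzyme Gzmb (1.17 ± 0.548 against 3.03 ± 0.948) and the chemokine Ccl5 (6.69 ± 3.47 against 13.1 ± 2.10). That list was called lower (adjusted p = 4.1e-12; adjusted p = 0.123 with an estimated correlation).

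**Figure D5:**
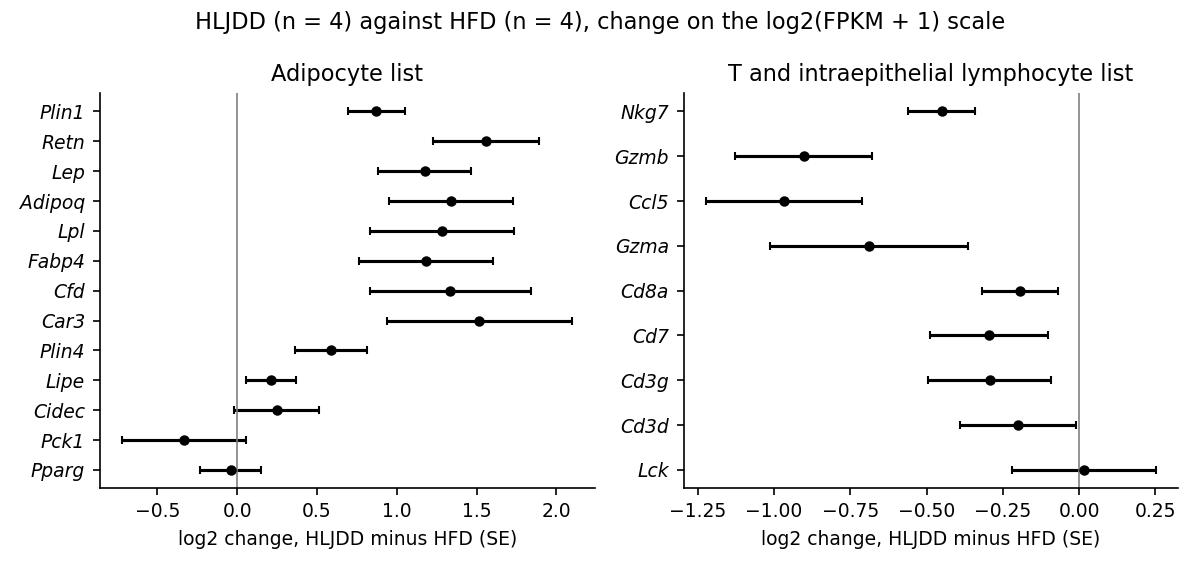
Difference between HLJDD and HFD on the log2(FPKM + 1) scale (horizontal axis) for each adipocyte gene (left) and each T and intraepithelial lymphocyte gene (right). Points are differences and bars their SE; 9 of 13 adipocyte genes were higher and 3 of 9 lymphocyte genes lower adjusted over the list alone, with Retn at 1.56 and Ccl5 at -0.97.

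Interferon-stimulated genes were lower as a list in HLJDD against HFD (median log2 difference -0.21, camera adjusted p = 6.5e-14; adjusted p = 0.277 with an estimated correlation), with 0 of 38 members past the threshold in either count by limma. The immunoproteasome genes Psmb8 and Psmb9 had log2 differences of -0.52 and -0.50. None of the members of the next lists passed over all genes by limma, as deposited or after scaling. The 13 class II antigen presentation genes (median -0.23) were called lower (adjusted p = 6.9e-05; adjusted p = 0.765 with an estimated correlation), but not without HFD replicate 1 in HLJDD vs HFD (0.123). The 16 Paneth cell genes were called lower too (adjusted p = 6.9e-05; adjusted p = 0.463 with an estimated correlation), but not without HLJDD replicate 4 (0.0602). Goblet cell genes were called lower (adjusted p = 0.00055; adjusted p = 0.314 with an estimated correlation), with Zg16 at 2267 ± 259 against 2901 ± 215 FPKM. Fatty acid synthesis genes, several of which fat cells also express, were called higher together with the adipocyte list (adjusted p = 0.00012; adjusted p = 0.644 with an estimated correlation). Of these 14, Scd1 (37.6 ± 12.1 against 16.5 ± 0.827) passed adjusted over the list alone.

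The fat absorption, cholesterol, distal and proximal lists were not called in HLJDD vs HFD, at camera adjusted p of 0.0602, 0.223, 0.113 and 0.807, and 0 of their members passed in either count by limma. The medians of the fat absorption, distal and proximal lists were 0.02, 0.01 and 0.10, while the camera direction was down for each. The fat absorption list was called lower without ND replicate 1 (0.0305), ND replicate 3 (0.0483), HFD replicate 2 (0.00014), HLJDD replicate 1 (0.0296) or HLJDD replicate 4 (0.00026), and the distal list without HLJDD replicate 3 (0.0029). Mitochondrially encoded transcripts were called lower (adjusted p = 0.0231; adjusted p = 0.891 with an estimated correlation). After scaling the value was 0.297, and without HFD replicate 1 (0.56), HLJDD replicate 1 (0.423), HLJDD replicate 3 (0.684) or HLJDD replicate 4 (0.306) it also missed the threshold, with the direction turned for the first and the third of these. Without both high-mitochondrial libraries 1 gene passed, the heat-shock gene Hsph1 (log2 difference 0.75, adjusted p = 0.0387; range over the alternatives 8.2e-05 to 1). With median-ratio scaling in addition no gene passed, and Hsph1 was at 0.0579.

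The comparison of HLJDD with ND asks what still differed between the decoction group and ND. Apoa4 stood at 16100 ± 4209 FPKM in HLJDD (n = 4) against 1429.9 ± 1310 in ND (n = 3), a rise of 4.05 (SE 0.59), and Fabp6 fell by 10.59 (SE 0.85). Interferon-stimulated genes fell in 31 of 38 cases and adipocyte genes rose in 9 of 13. By limma 1279 genes changed, 441 higher and 838 lower, and after median-ratio scaling 1011 were higher and 1063 lower. Camera called 14 of 41 lists higher and 8 lower, and 0 of them passed with an estimated correlation.

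The 10 largest rises were in Enpp3, Apoa4, Reg1, Ada, Slc46a1, Adh1, Nt5e, Bbox1, Aadac and Tm4sf4 (log2 changes of 3.25 to 4.33). The 10 largest falls were in Fabp6, Saa1, Slc10a2, Plb1, Tmigd1, Duoxa2, Fam151a, Mgat4c, Duox2 and Nos2 (-10.59 to -4.11). The Reg1 call (adjusted p = 0.0245) was lost without any 1 of the 3 ND libraries (0.103, 0.0928 and 0.0568), HLJDD replicate 1 (0.0656) or HLJDD replicate 4 (0.0651). The Fam151a call (0.0186) was lost without any 1 of the 3 ND libraries (0.0716, 0.0739 and 0.0537). With the region scores as terms the direction turned for Ada (-0.0362, adjusted p = 0.986, range over the alternatives 5.1e-07 to 0.986) and Fam151a (0.81, adjusted p = 0.805, range 8.6e-05 to 0.805). In that fit Reg1 was at 0.209 (adjusted p = 0.955, range 2.3e-06 to 0.955), and of these rises and falls only those of Adh1, Tm4sf4, Fabp6, Saa1 and Tmigd1 stayed past the threshold.

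Gip was higher in HLJDD than in ND by 1.12 (SE 0.27, adjusted p = 0.021; exact permutation p = 0.0286, the smallest that 35 arrangements allow). That call was lost without ND replicate 1 (log2 change 0.79, adjusted p = 0.108), ND replicate 2 (0.0829) or HLJDD replicate 1 (0.0539), and the range over the alternatives was 1.5e-06 to 0.42. A more distal stretch in ND cannot be told apart from a group effect on Gip here either. Of the 18 enteroendocrine genes, 2 rose and 4 fell, in both counts and after scaling, and the list was not called (camera adjusted p = 0.555). Ghrl rose to 9.496 ± 1.38 FPKM from 2.89 ± 0.78, and Pyy fell to 4.36 ± 4.30 from 33.8 ± 11.2. Gcg (log2 difference -0.96), Cck (0.38), Sct (-0.37) and Sst (-0.29) did not pass, at adjusted p of 0.182 to 0.683. Gcg was lower in all 4 HLJDD libraries than in the 3 ND libraries, with an exact permutation p of 0.0286 as deposited and after scaling.

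Interferon-stimulated genes were lower in HLJDD than in ND in 31 of 38 cases (36 adjusted over the list alone, 30 after scaling), with none higher (camera adjusted p = 7.5e-22; adjusted p = 0.0979 with an estimated correlation). Ifit1 fell from 28.9 ± 6.07 to 6.10 ± 1.72 FPKM and Ifit1bl1 from 38.8 ± 6.55 to 5.28 ± 0.84. Of 13 class II antigen presentation genes, 7 fell and none rose (7 lower and 4 higher adjusted over the list alone, 7 and 1 after scaling), with H2-DMb1 falling from 77.8 ± 2.89 to 6.76 ± 3.61, and the list was not called (adjusted p = 0.356). Of 9 T cell genes, 3 fell (5 adjusted over the list alone, 1 after scaling; camera adjusted p = 0.0547). The T cell list was called lower in HLJDD vs ND without ND replicate 3 (0.0184) or HLJDD replicate 2 (0.014). Of these Nkg7 was at 0.722 ± 0.108 against 1.56 ± 0.296 FPKM (adjusted p = 0.00993), lost without ND replicate 1 (0.0675) or ND replicate 2 (0.0679).

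Adipocyte genes rose in 9 of 13 cases (10 adjusted over the list alone, 11 after scaling) and none fell (camera adjusted p = 9.2e-12; adjusted p = 0.0749 with an estimated correlation). Adipoq rose from 1.65 ± 0.452 to 13.9 ± 5.30 FPKM, and Cidec, a lipid droplet gene that enterocytes also express, from 22.2 ± 9.99 to 81.5 ± 18.7. Fat absorption genes rose in 8 of 25 cases (10 adjusted over the list alone, 12 after scaling; adjusted p = 7.7e-07; adjusted p = 0.489 with an estimated correlation). Cholesterol synthesis genes fell in 16 of 26 with 1 higher (22 and 1 adjusted over the list alone, 20 and 1 after scaling; adjusted p = 6.9e-10; adjusted p = 0.424 with an estimated correlation), with Sqle at 4.75 ± 1.33 against 35.3 ± 14.7 FPKM.

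Of 8 bile acid genes, 1 rose and 5 fell, in both counts and after scaling (adjusted p = 0.0037; adjusted p = 0.424 with an estimated correlation). Of 14 distal genes, 9 fell and none rose (10 lower and 1 higher adjusted over the list alone, 10 lower after scaling; adjusted p = 3.3e-05; adjusted p = 0.424 with an estimated correlation). Of 12 proximal genes, 3 rose and 1 fell (6 and 1 adjusted over the list alone, and after scaling; adjusted p = 0.0014; adjusted p = 0.489 with an estimated correlation). Slc10a2 was at 0.258 ± 0.168 against 135 ± 124 FPKM, and the iron exporter Slc40a1, the proximal gene that fell, at 0.876 ± 0.154 against 6.54 ± 3.87.

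Goblet cell genes rose in 5 of 13 cases (6 adjusted over the list alone, and after scaling; adjusted p = 9.5e-05; adjusted p = 0.201 with an estimated correlation), with Zg16 at 2267 ± 259 against 910.5 ± 315.5 FPKM. Tuft cell genes fell in 5 of 9 (8 adjusted over the list alone, 5 after scaling; adjusted p = 0.00075; adjusted p = 0.489 with an estimated correlation). Xenobiotic and retinoid genes rose in 8 of 33 and fell in 2 (9 and 2 adjusted over the list alone, and after scaling; adjusted p = 3.3e-06; adjusted p = 0.597 with an estimated correlation). Protein digestion genes fell in 6 of 18 (10 adjusted over the list alone, and after scaling; adjusted p = 0.0064; adjusted p = 0.724 with an estimated correlation). Antimicrobial genes rose in 4 of 20 and fell in 6 (4 and 12 adjusted over the list alone, 4 and 5 after scaling; adjusted p = 0.0414; adjusted p = 0.465 with an estimated correlation), with Nos2 at 1.39 ± 1.46 against 35.6 ± 9.11. The antimicrobial call was lost in HLJDD vs ND without ND replicate 2 (0.0585), ND replicate 3 (0.157), HLJDD replicate 1 (0.0815) or HLJDD replicate 3 (0.23). None of the 13 mitochondrially encoded transcripts passed by limma. Their camera call (adjusted p = 0.025; adjusted p = 0.724 with an estimated correlation) was at 0.194 after scaling, 0.126 without ND replicate 3 and 0.842, with the direction turned, without HLJDD replicate 2.

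The count of 1279 genes was 435 without ND replicate 1, 438 without ND replicate 2, 802 without HLJDD replicate 1, 677 without HLJDD replicate 4 and 2556 without both high-mitochondrial libraries. After scaling, leaving out 1 library gave 906 (without ND replicate 1) to 2585 genes (without HFD replicate 1). With the proximal and distal scores as terms on median-ratio scaled values, 108 genes were called, where scaling alone called 2074. In that fit the changes of Apoa4 and Pyy were 1.70 and -0.12 (adjusted p = 0.473 and 0.919, the highest over their alternatives, from 2.7e-07 and 2.1e-06). Pyy is in the list behind the distal score, and the scores differ between the groups, so these losses do not separate region from group.

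The HFD and HLJDD groups were also compared through their shared references. Of the genes called against ND, 371 were higher and 720 lower in both HFD and HLJDD, and 0 went opposite ways (881, 870 and 0 after scaling). Independent lists would share 22.3 and 96.6, and unchanged groups simulated against the same ND libraries shared 0 in 99 of 100 simulations and 2606 in the other, more than the 1091 observed. Across genes the changes of HFD and HLJDD from ND correlated at 0.955 (0.529 simulated), with a covariance of 0.32 (0.0255 simulated). With HFD set against 1 ND library and HLJDD against the other 2, or the reverse, 6 splits gave a mean correlation of 0.875 (0.818 to 0.941) and a mean covariance of 0.305 (0.273 to 0.324). Genes are not independent replicates in these correlations.

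Among the 1786 genes changed in HFD against ND, 1368 (76.6%) had a difference of the opposite sign between HLJDD and HFD. The HFD libraries enter both comparisons, and with different HFD libraries in each, 6 splits gave a mean of 58.7% (36.1% to 81.4%). The correlation across genes was -0.315 with all libraries (-0.468 simulated with unchanged groups) and -0.071 on average over the splits (-0.366 to 0.14). This mean was 0.11 without HFD replicate 1, 0.061 without HLJDD replicate 3, -0.173 without HFD replicate 2, -0.171 without HFD replicate 4, -0.219 without HLJDD replicate 4 and 0.14 without both high-mitochondrial libraries, so its sign was not settled. The covariance was -0.033 against -0.0208 simulated, a difference of -0.0122. No gene called in HFD against ND was also called in HLJDD against HFD, where limma called 0 genes, 186 at an unadjusted p under 0.05 and 0 by limma-voom.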

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

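The tests of fat tissue, of library composition, of other hormone genes and of the gut region below, and the ratios after scaling, were chosen after the result was seen. Each value given as a ratio is the distance of 1 library from the nearest other library of its group, divided by the range of the group. The ratio was tested in 338 groups of 4 libraries, and 33 (9.8%) were past the critical value, where chance gives about 1 in 20 groups (5%). The ratios are of FPKM as deposited, which a high mitochondrial share lowers for all nuclear genes of a library. After median-ratio scaling, 20 of the 31 ratios of genes were still past the critical value for the same library, and 42 of 328 groups of genes were past it in all.

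In HLJDD replicate 2, lactase (Lct) stood at 90.4 FPKM against 296.6 to 324.8 in the other 3 libraries, a ratio of 0.88. The sugar transporter Slc5a1 (176.5 against 493.8 to 510.9; 0.949), the chylomicron gene Apoa1 (0.843), the hormone gene Cck (2.35 against 5.58 to 5.94; 0.901), Smpdl3a (0.896), Dbp (0.851), Hsph1 (0.837) and Tnfrsf13b (0.832) were lower as well. After scaling Lct and Dbp were still past the critical value (0.933 and 0.867), and Slc5a1 (0.724), Apoa1 (0.638), Cck (0.637), Smpdl3a (0.745), Hsph1 (0.501) and Tnfrsf13b (0.74) were not. The mitochondrial genes were higher, with COX2 at 4552 against 651.6 to 734.1 FPKM (ratio 0.979) and CYTB at 66348 against 16285 to 18157 (0.963). The ratios of the mitochondrial genes ND4, ND5, COX1, ATP6, ND2 and ND4L were 0.941, 0.92, 0.88, 0.861, 0.858 and 0.842. This library also stood apart in mitochondrial share (40.7% against 10.4% to 12.9%; 0.917) and in total reads (0.869).

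In HFD replicate 1, Tff3 was higher than in the other 3 libraries (ratio 0.975), and so was Sprr1a (0.832). Lower were Hsph1 (0.951), Dpp4 (0.923), Manf (0.923), the mucin gene Muc3a (0.908), Scg2 (0.715 against 3.11 to 3.54 FPKM; 0.848), Acaca (0.844), Acat2 (0.843) and Pcsk1 (0.836). After scaling Acaca (0.823), Acat2 (0.739) and Pcsk1 (0.783) were no longer past the critical value. HFD replicate 2 was higher in Saa1 (0.876), Slc10a2 (0.867) and the defensin Defa17 (36.2 against 0.687 to 5.94 FPKM; 0.852). HFD replicate 4 was lower in Ifit3 (0.871) and HLJDD replicate 4 higher in Ifit1bl1 (0.857), neither of them past the critical value after scaling. The 2 libraries with the most ratios past the critical value are also those with the highest mitochondrial share. Damaged or dying cells, a longer wait before RNA was taken and a difference between the animals were not tested as the source.

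The distal genes were high in ND, and of 12 proximal genes 4 were lower and 2 higher in ND than in HFD. The proximal gene Slc40a1 stood at 10.1, 7.08 and 2.42 FPKM in ND replicates 1, 2 and 3 and at 0.68 to 0.839 in HFD. Within ND it fell in the same order as the ileal gene Fabp6, where a shift along the gut would have it rise. The list scores did move as such a shift would have them, over only 3 libraries. From ND replicate 1 to 3 the proximal score rose (-1.125, -0.517 and -0.117) and the distal score fell (1.132, 0.977 and 0.515). Against library composition as the whole cause, 9 of 14 distal genes were still lower in HFD after scaling. A candidate explanation is a more distal stretch of gut in the ND samples. It predicts that ND libraries differ among themselves along the same genes. The 3 correlations across genes were 0.537, 0.432 and 0.092, with a mean of 0.354 (SD 0.233), and genes are not independent replicates. No value without such an axis was worked out. Residuals of libraries with different replicate numbers correlated at -0.609 to 0.53 after scaling, but they may hold the same axis and so give no such value. Without one, the 3 correlations within ND do not decide it. An effect of the diet on ileal genes, or on Gip against ND, cannot be told apart from a more distal stretch in ND. With scaling and the region scores as terms 171 genes were called, and groups made up 0.413 and 0.789 of the variance of the proximal and distal score.

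Gip was lower in HLJDD than in HFD, though not past the threshold over all genes. Against library composition as the cause, the log2 difference after scaling was -0.64 (SE 0.22). The other 17 hormone and granule genes had a smaller fall, with a median of -0.165 (SD 0.227), but 15 of 17 were lower too. A loss of enteroendocrine cells of every type is therefore not excluded. Against a different stretch of gut, the difference after scaling and with the region scores as terms was -0.67 (SE 0.22). Chance over all genes, fewer enteroendocrine cells of every type, fewer K cells and less Gip per K cell stay open.

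Adipocyte genes were higher in HLJDD than in HFD as a list, with 0 of 13 past the threshold over all genes by limma. The camera call was lost with an estimated correlation (adjusted p = 0.123). Against library composition as the cause, the median log2 difference of the list was 1.11 after scaling. A candidate explanation is more fat tissue in the HLJDD samples. It predicts that the 9 higher members, picked because they were higher in these data, move together within groups. Their mean pairwise correlation over 8 libraries was 0.82 (SD 0.153), where 1000 random sets of 9 genes reached at most 0.407. The other 4 members (Lipe, Cidec, Pck1 and Pparg), which enterocytes also express, correlated with them at -0.66 on average. Genes of 1 cell type would also move together if its share varied only within groups. The correlation therefore does not decide whether the HLJDD samples held more fat tissue. Whether any such fat tissue came from dissection or from the animals was not tested.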

How the results depend on the processing

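The fits without the 2 high-mitochondrial libraries, with scaling and replicate number together, and with the proximal and distal scores as terms were chosen after the result was seen; the others were fixed before the data were examined. Of 97 genes that the naming rule gave as changed in HFD against ND, 71 stayed past the threshold under all 12 other settings, 64 whichever of the 11 libraries was left out, and 23 under all 4 added fits. Of 69 in HLJDD against ND, these were 53, 51 and 13. Among the lists described in the text, 20 were called in HFD against ND, and the numbers were 14, 17 and 8. Of 9 such lists in HLJDD against HFD they were 6, 6 and 5, and of 13 in HLJDD against ND they were 9, 11 and 6. Ifit1bl1 and Fabp6 stayed past the threshold in HFD against ND in every fit that kept them.

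The number of genes changed in HFD against ND (1786) was 1145 with equal sums, 2695 with median-ratio scaling, 2804 with quantile normalization, 3053 without the 50 most abundant genes, 7702 with weights per library and 1080 with replicate number as a block. It was 3349 without the 2 high-mitochondrial libraries, 2948 when these were left out and the rest scaled, and 763 by unadjusted p with a 2-fold change. Scaling with the region scores as terms gave 171. Leaving out 1 library gave 617 (without ND replicate 1) to 3314 (without HLJDD replicate 2). For HLJDD against HFD (0 by limma, 186 at an unadjusted p under 0.05, 0 by limma-voom) it was 3807 with weights per library. It was 1 without the high-mitochondrial libraries (Hsph1, none with scaling as well) and 14 by unadjusted p with a 2-fold change. Scaling with the region scores as terms gave 2 (Ido1 and Lep). Leaving out 1 library gave 0 to 1 (1, Scd1, without HLJDD replicate 2, none with scaling as well). For HLJDD against ND (1279) it was 2074 with median-ratio scaling, 2297 with quantile normalization and 2133 without the 50 most abundant genes. It was 7082 with weights per library, 724 with the block, 2556 without the high-mitochondrial libraries and 2626 with scaling as well. Scaling with the region scores as terms gave 108, and unadjusted p with a 2-fold change 657. Leaving out 1 library gave 435 to 1695 (435 without ND replicate 1). Beyond having fewer libraries where some were left out, the cause was not tested.

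No pairing of the libraries by replicate number was detected. Over 10 pairs with the same number the correlations of residuals ran from -0.219 to 0.366, with a mean of 0.013 and 3 above 0.1. Over 30 pairs with different numbers they ran from -0.619 to 0.495, with a mean of 0.001. A weak pairing could be missed in this spread, so the counts with the block rest on no known pairing.

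For Gip in HFD against ND the log2 change was 1.61 with scaling and the region scores (adjusted p = 0.125, range 1.4e-07 to 0.125 over the settings). In HLJDD against HFD it was -0.51 with weights per library (adjusted p = 0.0062, range 0.0062 to 1). In HLJDD against ND it was 1.12 with no filter (0.0574), 1.05 with equal sums (0.0544) and 0.94 with scaling and the region scores (0.42). Without 1 library it was 0.79 to 1.45 (range over the settings 1.5e-06 to 0.42).

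With median-ratio scaling and the region scores as terms together, some genes changed sign against the fit as deposited. Scaling alone moved the median log2 change of all genes from -0.205 to -0.011 in HFD against ND, so the turns cannot be credited to the scores alone. In HFD against ND these were Acaca (0.0432), Acot2 (-0.19), Jun (-0.22), Mylip (0.0275), Ndufa5 (-0.0626), Onecut2 (-0.26) and Uqcrq (-0.0057), and in HLJDD against ND Ada (-0.0362), Fam151a (0.81), Nts (0.40) and Onecut2 (-0.52). Nts and Onecut2 are members of the lists behind the scores. In the same fit the direction of these lists turned in HFD vs ND, with camera adjusted p of 0.0267 for PPAR-alpha targets, 0.457 for oxidative phosphorylation, 0.582 for mitochondrial transcripts and 0.831 for immediate-early genes, and in HLJDD vs ND 0.724 for fat absorption and 0.070005 for mitochondrial transcripts. The mitochondrial list in HLJDD vs ND also turned without the high-mitochondrial libraries (0.807; 0.823 scaled), and ran from 0.00057 to 0.842 without 1 library (0.842 without HLJDD replicate 2). In HLJDD vs HFD it ran from 7.8e-17 to 0.684 (0.684 without HLJDD replicate 3), and the class II list turned without the high-mitochondrial libraries after scaling (0.911). The cause of these turns was not tested. Depth limits genes below 1 FPKM most.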

Other observations

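The tests below were chosen before the result was seen, except for the 3 lists described next, whose members were fixed beforehand but which were picked for mention afterwards. In HFD against ND the claudin gene Cldn4, part of the seal between epithelial cells, rose from 17.5 ± 3.38 to 112.4 ± 24.7 FPKM (adjusted p = 7.3e-05, and past the threshold whichever library was left out). Of 19 junction genes 1 rose and 4 fell (1 and 5 adjusted over the list alone, 2 and 3 after scaling), the latter including Tjp3, whose call was lost without ND replicate 2 (adjusted p = 0.0544), and camera did not call the list (adjusted p = 0.823). Of 12 sterol transport and LXR target genes 3 fell and none rose, in both counts (after scaling 2 rose and 3 fell), including the cholesterol importer Npc1l1 (187.3 ± 36.9 to 99.7 ± 15.8 FPKM). The Npc1l1 call was lost without any 1 of the ND libraries (0.0544, 0.103 and 0.094), HFD replicate 1 (0.0705) or HFD replicate 3 (0.0511), and the list was not called (adjusted p = 0.513). Of 17 immediate-early and heat-shock genes, which respond to handling of tissue, 4 rose (Jun, Fosb, Fos and Atf3) and none fell, in both counts (5 rose after scaling; camera adjusted p = 0.0031; adjusted p = 0.284 with an estimated correlation). The calls of Jun (0.085), Fosb (0.108) and Atf3 (0.104) were lost without ND replicate 1, and without ND replicate 2 those of Jun (0.0709), Fosb (0.107), Fos (0.0856) and Atf3 (0.108). Without ND replicate 3, Fosb (0.0661), Fos (0.107) and Atf3 (0.0766) lost theirs, and so did Fosb (0.0721), Fos (0.0658) and Atf3 (0.0601) without HFD replicate 3. Fos and Atf3 also lost theirs without HFD replicate 1 (0.0702 and 0.0722) or HFD replicate 4 (0.0598 and 0.0633).

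The gene counts against ND were larger for the real groups than for any other split of the libraries. With 35 splits the smallest share possible is 1 of 35, and libraries may share an animal, so chance is not excluded. Of 35 splits of the 7 libraries of HFD and ND, 1, the real one, gave as many as 1786 genes, and the highest other gave 333 (2695 and 990 after scaling). For HLJDD and ND 1 of 35, again the real one, gave as many as 1279, and the highest other gave 500 (2074 and 588 after scaling). For HLJDD and HFD the real split gave 0 genes by limma (186 at an unadjusted p under 0.05, 0 by limma-voom), so all 35 of 35 splits gave as many by construction, and the count of splits says nothing about chance there. The highest other split there gave 1458 genes, which points to a structure of the samples. It parted HLJDD replicates 1, 3 and 4 and HFD replicate 4 from the rest, the 4 libraries of these 8 with the lowest mitochondrial shares (10.4% to 12.9%), and gave 179 genes after median-ratio scaling.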
